A study of Homo sapiens with 3 samples.

How the data were processed

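Total RNA of MeT-5A cells was prepared as fragmented, adaptor-ligated libraries and sequenced in pairs on an Illumina instrument, per the labels' protocols. The labels give 3 libraries, 1 each for PBS, SKOV3 exosomes and A2780 exosomes. The submitters' processing notes name FastQC, Trimmomatic, HISAT2 and HTSeq, without roles, and the mouse build mm10. Which annotation supplied the gene models is not given in the sources used here.

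The authors deposited a table with 1 row per gene model that holds a name, a class, a position, a strand and a length. It also has 3 columns headed as counts and 3 headed as RPKM, per the file headers. These 6 columns were not used. Each is headed by 1 of the 3 codes A2, B1 and B2, and 0 of these occur as a whole word in the titles, descriptions, source names, characteristics or design text. A2 is the start of the word A2780 in the labels, while B1 and B2 start no word there. This partial match was not taken as a label, and assigning columns by order or by their values would have been a guess. The 3 deposited files of sequencing statistics carry the same codes and were not used either. Expression, library depth, fold changes and gene list shifts are therefore not reported, and none of the comparisons or alternatives fixed before the data were examined was run. The rule for naming genes, which ranked fold changes, could not be applied: the genes named here are members of the 28 lists fixed in advance, their older names and their partners on the opposite strand. The exceptions are a pair of transfer RNA models with very long spans and models with date-like names. These, and the partners from outside the lists, were named after their values were seen. The values reported are descriptions of the annotation, with no replicates and no statistical test; the closing section adds 3 checks of the annotation's origin.

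The length in the table is a number of bases per model. It equalled the span from start to end for 11517 models, exceeded it for 10 and was below it for the others. How it was derived is not given in the sources used here. Positions are printed as the table gives them. The table names no build, so its coordinates are not assigned to a particular assembly here. The human symbol tables used for names belong to GRCh38.p14, and their coordinates were used only for a comparison in the closing section; none is printed. Of 45817 model names, 42703 (93.2%) matched a human gene: 28590 by current symbol, 10681 by Ensembl identifier without its version and 3432 by a RefSeq symbol or synonym.

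lncRNA models were those in the classes lincRNA, antisense, sense intronic, sense overlapping, processed transcript and lncRNA. Overlap was counted between spans, at a minimum of 1 bp, on the same or on the opposite strand. For the fixed lists, transfer RNA models with a span above 1000 bp were not counted as partners, a limit set after the overlaps were seen. The alternatives were a minimum of 100 bp, a minimum of 50% of the lncRNA span, the addition of 2 small classes, the inclusion of those transfer RNA models, and a length minimum of 200 bp. The overlap procedure was tested on simulated data, where 0 of 1200 spans differed from a base-by-base count. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 were used.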

Results

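RNA was sequenced from MeT-5A, an immortalised human mesothelial cell line, after 48 h with PBS or with exosomes, small vesicles shed by cells, from SKOV3 or A2780 ovarian cancer cells. There was 1 library for each of the 3 treatments. The exosome dose was 50 ug. The question behind the design was how vesicles of each cancer line alter the transcripts of mesothelial cells, long non-coding RNAs (lncRNAs) in particular. Expression levels and the treatment comparisons are not analysed here. The 6 columns of per-library values carry the codes A2, B1 and B2, and 0 of these 3 codes occur as a whole word in the sample labels. A2 is also the start of the label A2780, but B1 and B2 start no word of the labels, and no label says what the codes stand for. No column was therefore assigned to PBS, SKOV3 exosomes or A2780 exosomes. With 1 library per treatment, a comparison would also have had no replicate check. The depth of each treatment's library is likewise not reported. What follows describes the genes over which the authors summarised their reads, and where the spans of neighbouring genes overlap.

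The table listed 45817 gene models, of which 19220 (41.9%) were protein-coding and 16157 (35.3%) belonged to 6 lncRNA classes. The lincRNA class, named for intergenic lncRNAs, was the most numerous of these classes, with 6090 models. The class named lncRNA held 4452 models and the antisense class 4403. The former also held 1483 models that overlapped a protein-coding gene on the opposite strand. The antisense count is therefore not a total of all antisense lncRNAs. Sense intronic transcripts contributed 671 models, processed transcripts 349 and sense overlapping transcripts 192. Most lncRNA models were not listed under a gene symbol: 11705 (72.4%) were named by an Ensembl identifier and 1541 by a provisional LOC name. The 11705 equals the size of the lincRNA, antisense, sense intronic, processed transcript and sense overlapping classes together. The naming may therefore follow the class of a model, which was not counted, rather than being a trait of lncRNAs. No protein-coding model was named by an Ensembl identifier (0 of 19220).

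lncRNA models were shorter than protein-coding models. The median length was 725 bp (quartiles 503 and 1615 bp) for the 6 lncRNA classes together and 2959 bp (quartiles 1806 and 4684 bp) for protein-coding genes. Within the lncRNA classes, the median ranged from 544 bp for sense intronic to 1378 bp for processed transcripts. It was 631 bp for lincRNA, 603 bp for antisense and 1346.5 bp for the class named lncRNA. The pooled median thus depends on the mix of classes, and the gap to protein-coding models differed by class. The protocol fragmented RNA to about 200 bp, and 3409 models (7.44%) were shorter than that. All 1857 microRNA models and all 447 transfer RNA models fell below this length, as did 413 of 431 small nucleolar RNAs. NEAT1, the scaffold of nuclear paraspeckles, was 22743 bp long, and MALAT1, an abundant nuclear lncRNA, was 8779 bp. GAS5, a host gene of small nucleolar RNAs, was 632 bp and SNHG6, another such host, 472 bp. The lengths are properties of the annotation and have no sampling error.

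**Figure D1:**
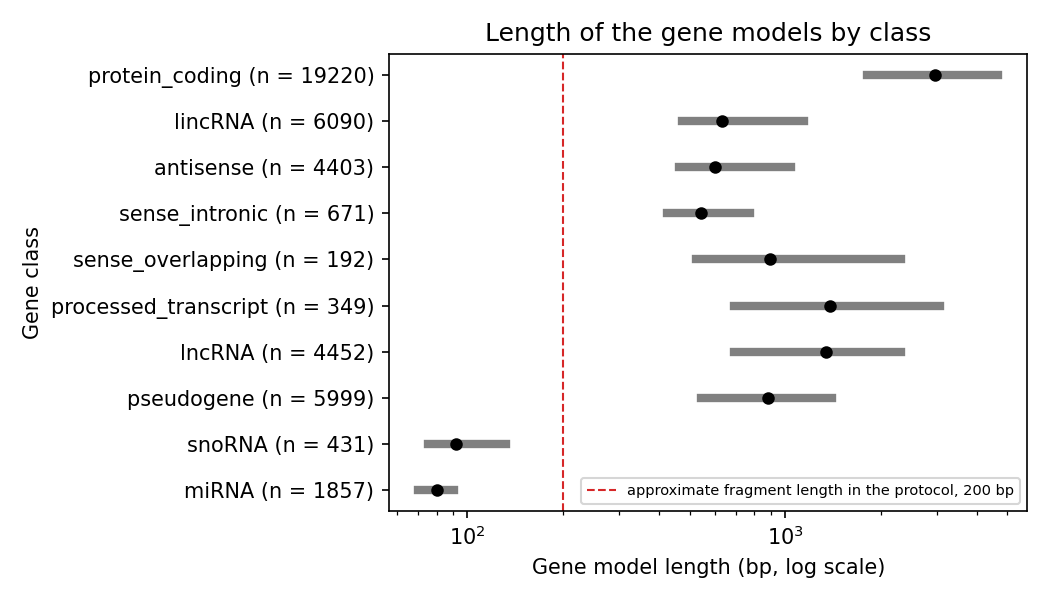
Gene model length in bp (x axis, log scale) for 10 gene classes (y axis, with the number of models). Points are medians, grey bars span the lower to the upper quartile, and the dashed line marks the approximate fragment length of 200 bp. The protein-coding median is 2959 bp, while the microRNA median is 80 bp and the small nucleolar RNA median 92 bp, both left of the line.

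Many lncRNA models lay across a protein-coding gene. On the opposite strand, 5406 of 16157 lncRNA models (33.5%) overlapped the span of a protein-coding gene by at least 1 bp, and on the same strand 1354 (8.38%) did. The share on the opposite strand was 78.7% in the antisense class (3465 of 4403) and 33.3% in the class named lncRNA (1483 of 4452). In the intergenic (lincRNA) class it was 5.39% (328 of 6090). The antisense and lincRNA classes are named for their position against other genes. Their shares may thus largely restate the class names, and the contrast is not read as a finding. Seen from the other side, 4236 of 19220 protein-coding genes had an lncRNA model on their opposite strand. Spans include introns, so an overlap of spans need not be an overlap of exons. The labels do not state whether reads were counted by strand. Without strand, reads from the shared exons of such a pair cannot be separated.

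The 28 gene lists fixed before the data were examined held 526 gene names, of which 501 were listed under that name. Some of the other names are synonyms of genes that were listed. Of these 501, 188 (37.5%) had at least 1 model of any class on the opposite strand, called a partner here. The matching share over all models was not computed, and genes differ in span. Neither this share nor a difference between lists is therefore read as a property of the listed genes. A pair of transfer RNA models was not counted as partners, because their spans run over separate loci: TRNAN-GUU, of 148 bp, spans 127032826 bp of chromosome 1, and TRNAA20, of 146 bp, spans 40626 bp of chromosome 6. All 16 genes of mesothelial identity were listed, and 5 of them had such a partner. MSLN, the surface protein mesothelin, lay on chromosome 16 from 810765 to 818865 with no partner. CALB2, the calcium-binding mesothelial marker calretinin, lay on chromosome 16 from 71392616 to 71424341, also without one. WT1, a transcription factor of mesothelium, on chromosome 11 from 32409321 to 32457081, was overlapped by the antisense model WT1-AS. KRT18, a keratin of simple epithelia, overlapped the span of its filament partner KRT8 on the opposite strand.

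All 21 mesenchymal and epithelial-to-mesenchymal transition (EMT) genes were listed, and 10 had a model on the opposite strand. VIM, the intermediate filament vimentin, on chromosome 10 from 17270258 to 17279592, met VIM-AS1, a model of 1992 bp that began at 17256238 and ended at 17271984. ZEB1 and ZEB2, transcription factors of EMT, met ZEB1-AS1 and ZEB2-AS1. SNAI1, another EMT factor, and FN1, fibronectin, had none. All 18 epithelial junction genes were listed, 9 of them with a partner. CDH1, the adhesion protein E-cadherin, was among these 9, and the epithelial adhesion molecule EPCAM was not. The collagen and matrix list was complete at 24 genes, 12 with a partner, and COL1A1 was free of one. In the integrin and adhesion list 12 of 19 genes had a partner, as did 11 of 18 p53 targets.

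Lists of cell responses were nearly complete. All 28 inflammatory genes were present, 5 with a partner, and all 26 interferon response genes, 7 with a partner. The lists for hypoxia and glycolysis (22 genes, 10 with a partner), proliferation (28 and 9), cholesterol synthesis (20 and 9), unfolded protein and ATF4 (20 and 6), heat shock (12 and 3) and NRF2 and metallothioneins (18 and 6) were complete. So were the proteases and inhibitors (18 and 9). Of 21 TGF-beta response genes 19 were listed, 8 with a partner; of 20 immediate early genes 19, 5 with a partner; and of 16 YAP and TEAD targets 14, 7 with a partner. The genes missing from these 3 lists were CCN1 and CCN2, matrix-associated signalling proteins, which were present under their older names CYR61 and CTGF.

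Markers of other cell types were listed too. The fibroblast (11 genes, 3 with a partner), leukocyte (12 and 3) and endothelial lists (10 and 4) were complete, as were the exosome and vesicle pathway (16 and 6) and the blood and serum background (9 and 1). Of 18 ovarian carcinoma line markers 17 were listed, 6 with a partner, and CD24 was not among the models analysed here. All 22 ribosomal protein genes were listed, 4 with a partner. Of 21 histone names 14 were listed, 1 with a partner; the other 7 are newer names of histone genes already in the list under their older ones. None of the 13 mitochondrially encoded protein genes was among the models analysed here: the 24 models on the mitochondrial chromosome were 22 transfer RNAs and 2 ribosomal RNAs.

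Of 50 lncRNA names fixed in advance, 48 were listed, and 22 of these had a model on the opposite strand. LINC00152, 1 of the 2 names not listed, is an older name of CYTOR, which was listed. MALAT1, on chromosome 11 from 65265209 to 65273987, was overlapped by TALAM1, an antisense model of 8121 bp from 65266783 to 65274903. KCNQ1OT1, an imprinted antisense transcript of 91671 bp, lay across KCNQ1. HOTAIR, a lncRNA of the HOXC cluster, lay across HOXC11, and HIF1A-AS2 lay across HIF1A. H19, an imprinted lncRNA, lay across HOTS, and GAS5 lay across GAS5-AS1. NEAT1, DANCR, NORAD and SNHG1 had no model on the opposite strand. TALAM1, VIM-AS1 and the other partners from outside the fixed lists were named after their overlaps were seen. CRNDE, placed in the lncRNA list, was annotated as protein-coding.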

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

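The alternatives fixed before the data were examined (scaling, filters, pseudocount, fold threshold, counting error and unit) were not run, because they act on expression values that are not analysed here. The alternatives below were chosen after seeing the data. Opposite-strand overlap of lncRNA models with protein-coding genes was 5406 models at 1 bp, 5282 at 100 bp and 3773 when 50% of the lncRNA span was required. Same-strand overlap went from 1354 to 1337 and 1114 under the same 2 settings. Adding the 2 small classes gave 5424 and 1376, and 16196 lncRNA models in place of 16157. Counting the transfer RNA models that run over separate loci as partners gave 198 fixed-list names with a model on the opposite strand, in place of 188. Requiring 200 bp left 16018 lncRNA models. Each of these counts stayed within 1.5 times its main value. Within that limit, the opposite-strand share still fell from 33.5% at 1 bp to 23.4% when 50% of the lncRNA span was required. No paired analysis was possible because the result comes from no test and there is 1 library per treatment. Depth limits were not assessed.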

Other observations

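A check of the species of the gene identifiers was planned before the data were examined. The form of the 3 checks of the annotation in this part, all tests without a p-value, was chosen after the table had been looked at. The submitters' processing notes list the mouse build mm10, while the labels describe human cells. The gene models argue against a mouse annotation: they occupy 22 autosomes, 2764 of them lie on chromosomes 20 to 22, which the mouse lacks, and 0 of the 11726 Ensembl identifiers are mouse identifiers. The build's place in the notes was not explained by any value here. The tables also argue against coordinates of the current human assembly. Of 30417 models with the same symbol and chromosome in GRCh38.p14, 72 (0.237%) had an identical start and end. Gene boundaries redrawn on the same assembly would move starts and ends separately, whereas in 11795 of these models (38.8%) both ends differed by one and the same number of bases, with a median of 395880 bp. The coordinates were compared with no other human assembly, so which assembly the table used was not determined here. No biological explanation was tested for either pattern.

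A set of 27 models carried names that read as calendar dates, such as 1-Mar, 10-Sep and 1-Dec. They used 25 distinct names, because 1-Mar and 2-Mar each occurred in 2 models. The models named 1-Mar lay on chromosomes 1 and 4, and those named 2-Mar on chromosomes 1 and 19. Gene lists matched by symbol miss these models.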
